A study of Mus musculus with 8 samples.

How the data were processed

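The ascending thoracic aorta of 3 young wild-type mice was measured by droplet single-cell RNA sequencing with hashtag antibodies. Per the labels' protocols, enzymes (type II collagenase at 10 mg/mL, elastase at 1 mg/mL) acted on the tissue for 60 min and 37 °C. The suspension was passed through a 70 µm strainer and depleted of dead cells, and about 15000 viable cells per sample were loaded on a Chromium instrument. The series lists 4 gene expression and 4 hashtag libraries, and the deposited files hold 1 matrix with a single barcode suffix, so a barcode cannot be traced to a library. Per the labels, each of 3 TotalSeq-B hashtags marks 1 age. The design written before the data were examined took the match of hashtag to age as not given; the deposited hashtag reference gives hashtags 1, 2 and 3 as 11, 12 and 13 weeks, and these ages are used here. With 3 mice and 3 ages, each hashtag is read as 1 animal.

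The deposited matrix holds raw UMI counts per gene and per hashtag, not normalized, written by Cell Ranger 6.0.1 per the file headers. The genome build mm10 and Seurat 4.0.5 are named in the submitters' processing notes, and the annotation is not given in the sources used here. The values were checked to be whole numbers, with 32285 genes, 3 hashtags and 48467 barcodes. Of the gene IDs, 32158 matched the reference table of gene names and 31436 carried the same symbol there. 40 symbols were shared by more than 1 ID and stayed separate. No genome of this build was used here, so no coordinates are given.

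Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which left 7154 of 48467 barcodes. Scrublet (scanpy 1.11.5, expected rate 0.06) marked 1 of the 7154 barcodes as a doublet; a caller that marks so few has not worked, and doublets of cells from the same animal stay in the data. Hashtags were assigned with HTODemux in Seurat 5.3.0 on centred log ratios per hashtag, with a positive quantile of 0.99, and only barcodes with a single hashtag entered the tests. Counts were normalized per cell, the 2000 most variable genes outside the fixed lists were reduced to 30 principal components, and a graph of 15 neighbours was clustered by the Leiden algorithm at resolution 0.5, or 0.3 within a class. Clusters were called X-like from marker lists fixed before the data were examined, when at least 3 markers were each detected in at least 10% of the cluster's cells and the list's mean log2 ratio to the lowest cluster, after adding 10 CPM to each, was at least 1. A cluster with more than 1 marker of another list among its 10 leading genes, and fewer of its own, stayed unnamed, as did one in which most cells held over 1% haemoglobin UMIs, unless at least 3 erythroid markers led it.

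Several choices were made after the data were seen. The scoring rule for cluster names was revised 3 times while the markers stayed fixed. The design named HTODemux on centred log ratios without saying over what they are centred, and both forms were run before 1 was kept. Centring per cell left 17, 91 and 98 SMC-like and 9, 21 and 20 fibroblast-like cells in the 3 hashtags, too few for the planned tests. Centring per hashtag, the default of Seurat, left enough and was kept with that result known; the per-cell form is given among the alternatives. A caller built on the ratio of the 3 hashtags to their background composition was added, which calls a barcode when its highest hashtag lies at least 4 standard deviations above background and the next at most 2. SMC-like clusters 1 and 8 have 1 marker of another class each (Tnnt2 and Rgs5) and 0 smooth muscle markers among their 10 leading genes, because smooth muscle transcripts are abundant in most clusters; they were named from the mean of all smooth muscle markers, and genes are also given by cluster where hashtag samples are compared. Subclusters with at least 2 markers of another class, erythroid markers aside, among their 10 leading genes were called mixed and kept in the main comparisons. The macrophage-like and subcluster comparisons did not reach the planned 50 cells per hashtag and are given with a minimum of 10. The comparison of the 2 largest SMC-like clusters was added.

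For each comparison, counts were summed per hashtag and class and tested with edgeR 4.0.16 (R 4.3.3) by glmQLFit and glmQLFTest, with TMM scaling, filterByExpr and the hashtag as a block, since the classes come from the same animals. Levels beside a test are CPM (counts scaled to a common total) with TMM scaling, and elsewhere CPM of the total UMIs of the sample or class. P-values were adjusted by the Benjamini-Hochberg method and genes were called at an adjusted p under 0.05. All named classes with enough cells shared a fit: the fibroblast-like, endothelial-like and SMC-like classes for the first pair of comparisons, and 5 classes for the macrophage-like one. The 3 sums per class are the replicates. A p-value sets a class difference against the spread left once hashtag differences shared by the classes are removed. That spread is estimated over all classes of the fit, not from the compared classes alone. The SE given with a fold comes from the same test. It can be smaller than the SE of the 3 sample ratios. Sums built from wrongly assigned barcodes would resemble random parts of the pooled cells and would vary less than animals do, so p-values of classes with weak hashtag signal can be too small. The block follows from the design, in which a hashtag is an animal. The values themselves gave no sign of the pairing: the correlation of same-hashtag deviations between the classes compared was -0.0463 to 0.125 over the comparisons. Lists were tested with limma 3.58.1 camera at a preset correlation of 0.01 and with an estimated correlation. For each list called at the preset correlation, the median and the mean log2 fold change had the direction of the test.

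The 13 gene lists, with 221 distinct genes, were fixed before the data were examined and left out of the clustering, so that they do not define the classes. The 12 lists reported here cover elastic fibres and microfibrils, interstitial collagens, basement membrane, matrix crosslinking, proteases and inhibitors, proteoglycans, integrins and focal adhesion, mechanosensitive channels and receptors, the Hippo pathway, the TGF-beta pathway, heritable thoracic aortic disease and dissociation stress. Another list is left out of the text, and its genes stay in the counts over all lists and in the adjustment. The genes named were chosen by a rule fixed beforehand. From each list it takes the 2 genes of largest absolute log2 fold change with an adjusted p under 0.05, the same direction in all 3 hashtag samples and at least 20 CPM in 1 of the classes. It takes 1 per list for subclusters, and always adds Eln, Fbn1, Col1a1, Col3a1, Lox, Ccn2, Piezo1, Yap1, Itgb1 and Tgfbr2. Where a gene had 0 counts in a group, the fold is a lower bound against 3 counts over the group; where it had 1 to 3 counts, the ratio of counts is given with its exact 95% interval. Intervals and such bounds cover counting error only.

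Each test was tested on simulated data with 200 genes changed by known folds. In the fibroblast-like comparison it recovered 66% of genes changed 2-fold and 93% of those changed 4-fold, over 7797 genes, with 6.47% of its calls false. The shares recovered were 70% and 93% for the endothelial-like comparison over 7797 genes, 48% and 82% for the macrophage-like one over 7095, 23% and 52% for the SMC-like subclusters over 7576, 54% and 79% for the fibroblast-like subclusters over 1724, and 76% and 94% for SMC-like clusters 3 and 1 over 8059. False calls made up 9.94%, 3.70%, 2.60%, 1.48% and 7.10% of these calls. Simulated genes had their mean level over all classes of the fit, the fitted spread and no difference between hashtag samples. The rates thus do not cover wrongly assigned barcodes, genes low in 1 class or comparisons in which far more genes change. No list was called in any of the simulations, which drew genes independently and changed no list as a set. They cannot show how often lists are called wrongly when the genes of a list vary together. Alternatives covered RLE size factors, DESeq2 1.42.0, no low-count filter, no hashtag block, each hashtag sample left out, only the 2 classes in the fit, other hashtag callers and quantiles, other cell filters, another resolution and clustering with the fixed lists. Clustering used igraph 0.11.9 and scikit-learn 1.9.0 under Python 3.11.15, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.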

Results

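The transcriptomes of cells from the ascending thoracic aorta of 3 young wild-type mice were collected in 1 pooled droplet library set, with a hashtag antibody for each animal, at 11, 12 and 13 weeks of age. The matrix holds 166848700 gene UMIs and 44898085 hashtag UMIs over 48467 barcodes, with a median of 2389 UMIs and 1024 genes per barcode and 15.7% mitochondrial UMIs. Haemoglobin transcripts made up 4.25% of all gene UMIs. The cell filter kept 7154 barcodes, with a median of 7206 UMIs and 2480 genes. The SMC-like cells (smooth muscle cells named from marker genes) of the 3 hashtag samples held 2928623, 1835556 and 2235557 UMIs, the fibroblast-like cells 657252, 413838 and 436899, and the endothelial-like cells 616694, 575216 and 693823. There is 1 sample per age and no other group, so the tests compare cell classes within the same animals and no test was made between ages.

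Which barcode came from which animal was read from the hashtags. HTODemux assigned 1609 of the 7154 barcodes to a single hashtag (22.5%, exact 95% interval 21.5 to 23.5%), 665 to hashtag 1, 427 to hashtag 2 and 517 to hashtag 3. It found several hashtags on 1871 barcodes (26.2%) and no hashtag on 3674 (51.4%). Hashtag 1 had a median of 115 UMIs per barcode over all barcodes against 337 and 352. The share with a single hashtag depended on the caller and the filter, from 11.4% with centring per cell to 32.6% with the stricter cell filter, which kept 178 barcodes. A caller on the ratio of the hashtags to background gave 28.1%. Where HTODemux gave hashtag 1, 2 or 3, the ratio caller gave the same hashtag to 373 of 665, 332 of 427 and 407 of 517 barcodes and another hashtag to 0.

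The cellular makeup of the young ascending aorta is what the series maps. SMC-like cells, the contractile cells of the media, made up 51.0% ± 0.833 of single-hashtag cells (mean ± SD, n = 3 hashtag samples). Endothelial-like cells, which line vessels, made up 15.6% ± 2.09, fibroblast-like cells, the main matrix producers of the adventitia, 14.0% ± 1.28, and macrophage-like cells 4.39% ± 2.90. Erythroid-like cells made up 5.97% ± 1.38, B-like cells 0.816% ± 0.506, mesothelial-like cells 0.743% ± 0.0355 and pericyte-like cells 0.722% ± 0.430, and 6.71% ± 4.23 stayed unnamed. The erythroid-like cells held Acta2, Tagln and Myh11 at 13910.5, 10228 and 4901 CPM, against 14529, 10903 and 5154 in SMC-like cells. They were thus not told apart from SMC-like barcodes with haemoglobin RNA, which would leave the SMC-like share too low. Over all 7153 cells, whatever their hashtags, the endothelial-like share was 5.59% (400 cells), the SMC-like share 53.7% (3839 cells), the fibroblast-like share 15.6% (1115 cells), the macrophage-like share 1.58% (113 cells) and the unnamed share 16.0% (1144 cells). The SMC-like mean over hashtag samples was 29.9% with the stricter cell filter, 22.9% with centring per cell and 31.4% at up to 20% mitochondrial UMIs. In the endothelial-like class it was 46.3% with the stricter filter, 36.8% with centring per cell, 24.8% with mixture calls and 9.43% at resolution 1.0. Centring per cell gave 6.33% fibroblast-like and 9.49% macrophage-like cells, and the stricter filter 23.8% fibroblast-like ones. Erythroid-like cells made up 11.5% at resolution 1.0, 12.2% with the lists kept in the clustering and 2.72% with centring per cell. B-like cells made up 3.38% with centring per cell and 1.79% with mixture calls. Mesothelial-like cells made up 1.30% with mixture calls, 1.32% with centring per cell and 0.421% with the lists kept. Pericyte-like cells made up 0.369% with centring per cell, and unnamed ones 16.7% with centring per cell and 37.9% at up to 20% mitochondrial UMIs.

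Single samples stood apart for some classes. The macrophage-like share was 7.74% in hashtag 3 against 2.86% and 2.58% in hashtags 1 and 2, and the unnamed share was 11.6% in hashtag 1 against 4.69% and 3.87%. Mixture calls and ratio calls left the same samples highest. With centring per cell, hashtag 1 was highest for the macrophage-like share (14.4%, 4.01% and 10.1% in hashtags 1, 2 and 3). It was lowest there for the unnamed share (3.03%, 24.4% and 22.7%), so both orders depended on the caller. With 1 animal per age these differences have no replicates and were not tested. The 2 largest SMC-like clusters held 2570 and 1084 cells. The first was led by Tnnt2, a troponin, and Ptprz1, a receptor phosphatase, and the other by Pln, which regulates the calcium pump of the sarcoplasmic reticulum, and Mgp, an inhibitor of calcification. Fibroblast-like cells formed a cluster led by Pi16 and Clec3b (603 cells) and one led by Lum and Serpinf1 (512 cells), and endothelial-like cells one led by Gpihbp1 and Fabp4, known from capillaries (318 cells), and one led by Vwf, Lyve1 and Bmx (82 cells), which also scored for lymphatic markers (4.52, against 5.25 for endothelial ones). Acta2, the smooth muscle actin, stood at 14529 CPM in SMC-like and 13910.5 in erythroid-like cells. It stood at 8904 CPM in B-like, 7412 in macrophage-like, 7410 in endothelial-like and 3076 in fibroblast-like cells. Smooth muscle transcripts were thus abundant in classes that should lack them. In the unnamed cluster, 88.8% of cells held over 1% haemoglobin UMIs.

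**Figure D1:**
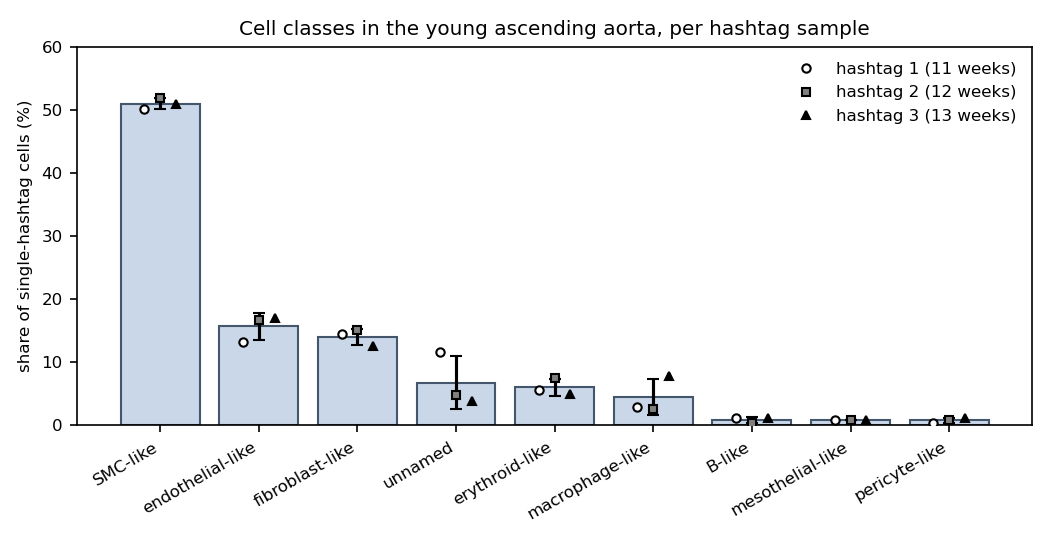
Share of single-hashtag cells (%, vertical axis) in each cell class (horizontal axis). Bars are means over the 3 hashtag samples with the SD and points are single samples. SMC-like cells make up 51.0%. With these calls the macrophage-like share of hashtag 3 (7.74%) stands above the other samples, which centring per cell did not keep.

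How the matrix and force-sensing genes of adventitial cells differ from those of the media is asked by comparing fibroblast-like with SMC-like cells. Fibroblast-like cells had higher levels of most interstitial collagen and protease genes, and SMC-like cells of Eln and of most integrin genes. Fbn1, the main protein of microfibrils, stood at 885 ± 265 CPM in fibroblast-like and 177 ± 9.48 in SMC-like cells (mean ± SD, n = 3), a log2 fold change of 2.30 ± 0.12 (SE; adjusted p = 1.79e-13, edgeR quasi-likelihood, higher in 3 of 3 samples). Eln, which encodes elastin, was lower, at 560.2 ± 122 against 1734 ± 143 CPM (-1.64 ± 0.14; adjusted p = 1.15e-09, edgeR, lower in 3 of 3 samples). Tgfbr2, a receptor of TGF-beta, was higher (2.37 ± 0.12), and Itgb1, the beta chain shared by many matrix receptors, was lower (-1.44 ± 0.11). Values given after a gene here and below are log2 fold changes ± SE, and named genes with a call had the same direction in 3 of 3 samples, except Lox in macrophage-like cells.

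Where a list has no count adjusted over the list alone, that count was the same. Of 13 interstitial collagen genes tested, 11 were higher in fibroblast-like cells, 1 was lower and 1 did not pass (11 and 1 adjusted over the list alone; 11 and 0 with DESeq2). The list as a set was higher by limma camera (adjusted p = 0.00120; adjusted p = 0.319 with an estimated correlation). The largest changes were in Col5a3, a chain of collagen V (5.90 ± 0.53), and the fibril-associated Col14a1 (3.06 ± 0.11). Col5a3 had only 4 UMIs in SMC-like cells, so the size of its fold is uncertain. Col1a1 and Col3a1, the chains of the most abundant fibrils, changed by 1.05 ± 0.12 and 0.81 ± 0.12. Among 14 protease and inhibitor genes 10 were higher and 2 lower (10 and 2 adjusted over the list alone; 10 and 0 with DESeq2), led by Mmp2, a gelatinase (4.10 ± 0.16), and Ctsk, a collagen-degrading cathepsin (3.61 ± 0.30). The set was higher by camera (adjusted p = 0.00120; adjusted p = 0.117 with an estimated correlation). The crosslinking and processing list had 8 higher and 2 lower of 16 (8 and 2 adjusted over the list alone). Pcolce2 and Pcolce, enhancers of procollagen cleavage, were higher (4.70 ± 0.15 and 4.22 ± 0.18), and Lox, a crosslinker of collagen and elastin, was lower (-0.78 ± 0.16). Of 11 proteoglycan genes 7 were higher and 3 lower (7 and 3 adjusted over the list alone), led by Fmod (4.67 ± 0.39) and Podn (3.22 ± 0.44), small proteoglycans of the matrix.

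Elastic fibre and basement membrane genes went both ways. Of 16 elastic fibre and microfibril genes 7 were higher and 7 lower (7 and 7 adjusted over the list alone; 7 and 3 with DESeq2). The higher ones included Emilin2 (7.12 ± 0.33) and Fbln1 (4.96 ± 0.18), glycoproteins bound to elastic fibres. Emilin2 had only 5 UMIs in SMC-like cells, so the size of its fold is uncertain. Of 14 basement membrane genes 5 were higher and 7 lower (5 and 7 adjusted over the list alone). Nid1, which links laminin to collagen IV, was higher (6.55 ± 0.17), and Lamb1, a laminin chain, had 104 UMIs in fibroblast-like against 1 UMI in SMC-like cells, a ratio of 483 in CPM (exact 95% counting interval 84.8 to 19248). Among 16 genes of heritable thoracic aortic disease 6 were higher and 5 lower (6 and 5 adjusted over the list alone), with Mfap5, a microfibril protein, at 2.99 ± 0.11.

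Of 26 integrin and focal adhesion genes, 17 were lower in fibroblast-like cells and 4 higher (17 and 4 adjusted over the list alone; 16 and 2 with DESeq2), with Itga8 (-2.21 ± 0.16) and Itga3 (-2.07 ± 0.33) the most changed. The set was lower by camera (adjusted p = 0.000373; adjusted p = 0.117 with an estimated correlation). Of 14 mechanosensitive channel and receptor genes 3 were higher and 5 lower (3 and 5 adjusted over the list alone; 2 and 1 with DESeq2). Cav1, the protein of caveolae (-1.35 ± 0.13), and the cation channel Trpv2 (-1.74 ± 0.49) were lower. The stretch-gated channel Piezo1 was higher (1.02 ± 0.36; adjusted p = 0.0291, edgeR, higher in 3 of 3 samples). Of 20 Hippo genes 4 were higher and 4 lower (4 and 5 adjusted over the list alone). The target genes Ccn1 and Ccn2 were lower (-1.78 ± 0.15 and -1.41 ± 0.10), as was Tead3, a partner of the co-activator Yap1 (-1.52 ± 0.38), and Yap1 itself did not pass (-0.19 ± 0.23). In the TGF-beta list 5 of 16 were higher and 3 lower (5 and 4 adjusted over the list alone), including the receptor Acvrl1 (1.74 ± 0.23). Of 12 dissociation-stress genes, which respond to tissue digestion, 0 were higher and 4 lower (0 and 4 adjusted over the list alone), with Fos at -1.75 ± 0.20 and Atf3 at -1.51 ± 0.37.

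In this comparison edgeR's quasi-likelihood test called 1479 of 7797 genes higher and 1385 lower (1079 and 807 with DESeq2), and 66 higher and 65 lower among 189 genes of the fixed lists. A subcluster with 19.4% of fibroblast-like cells carried smooth muscle transcripts (Acta2 9149.7 CPM, against 803 in the largest subcluster), and Hbb-bs stood at 8497 CPM in fibroblast-like against 1138 in SMC-like cells. Without such subclusters the log2 fold change was -2.46 for Eln, -2.11 for Itgb1, -4.57 for Itga8 and -2.17 for Ccn2. The call of Piezo1 was lost in 8 of 18 alternatives (edgeR or DESeq2 adjusted p from 0.000449 to 0.255 over all of them). That of Trpv2 was lost in 3, among them those without hashtag sample 1 and without 3 (5.91e-06 to 0.142) and that of Tead3 in 1 (7.14e-06 to 0.0525), and leaving out any 1 sample ended that of Piezo1. The folds of 19 of 32 named genes moved by over 1.5 times in at least 1 alternative.

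**Figure D2:**
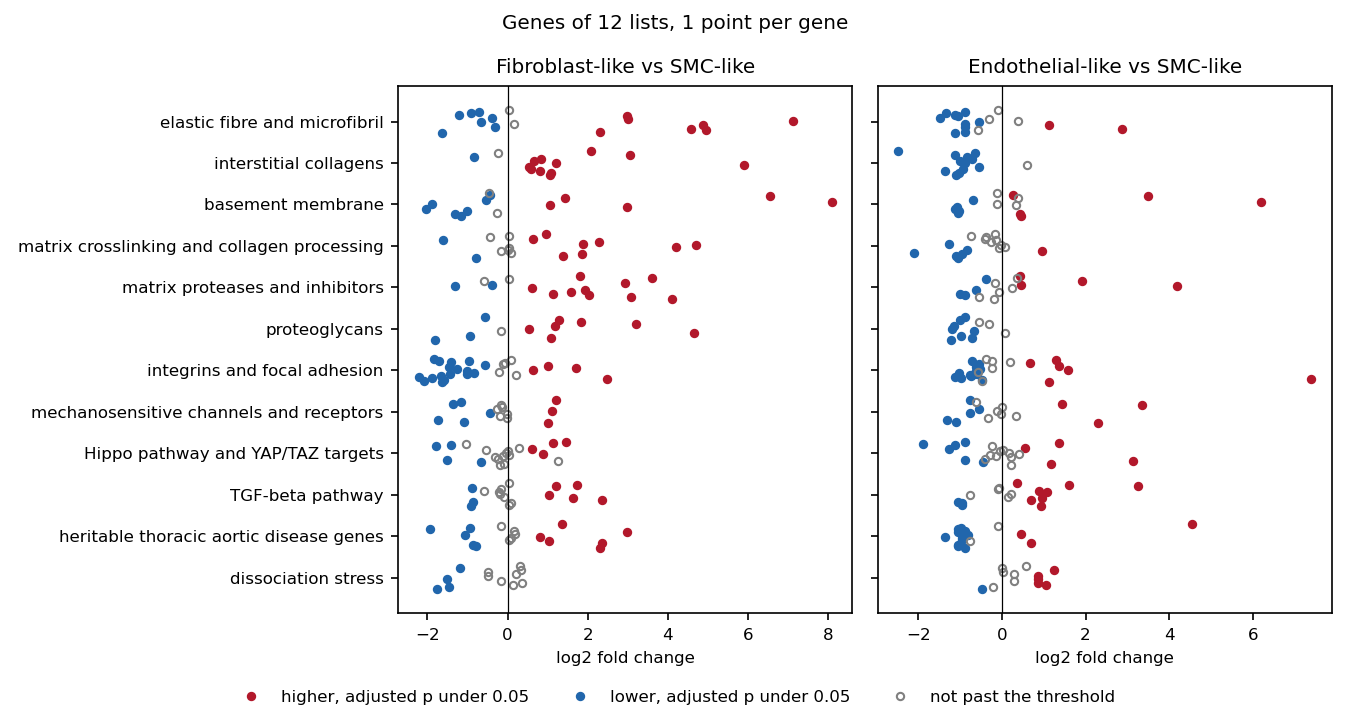
Log2 fold change (horizontal axis) of each tested gene of 12 fixed lists (vertical axis), 1 point per gene, for fibroblast-like over SMC-like cells (left) and endothelial-like over SMC-like cells (right). Colour gives the call at an adjusted p under 0.05; most interstitial collagens lie right of 0 in fibroblast-like cells (11 of 13 called) and left of 0 in endothelial-like cells (12 of 13 called).

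The comparison of endothelial-like with SMC-like cells asks which of the same gene groups mark cells that line vessels. Of the 400 endothelial-like cells, 318 lay in the cluster led by Gpihbp1 and Fabp4, known from capillaries. The values are therefore not those of the lining of the aorta alone. Endothelial-like cells had lower levels of most interstitial collagen genes and of most elastic fibre genes, and higher levels of single receptor genes such as Piezo1 and Notch1, while the list of mechanosensitive channels and receptors did not pass as a set (camera adjusted p = 0.901). Piezo1 stood at 42 ± 12.8 CPM against 8.38 ± 1.91 in SMC-like cells, a log2 fold change of 2.31 ± 0.26 (adjusted p = 1.25e-07, edgeR quasi-likelihood, higher in 3 of 3 samples). Notch1, a receptor of cell contact signalling, was higher (4.53 ± 0.18), as were Plxnd1, known as a sensor of shear stress (3.36 ± 0.22), and the TGF-beta family receptors Eng (3.25 ± 0.13) and Acvrl1 (1.60 ± 0.22). Eln was lower, at 794 ± 184 against 1734 ± 143 CPM (-1.12 ± 0.14; adjusted p = 4.23e-07, edgeR, lower in 3 of 3 samples).

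Of 13 interstitial collagen genes 12 were lower in endothelial-like cells and 0 higher (12 and 0 adjusted over the list alone; 8 and 0 with DESeq2), with Col3a1 at -1.35 ± 0.13, Col14a1 at -1.12 ± 0.14 and Col1a1 at -1.09 ± 0.13. The set was lower by limma camera (adjusted p = 9.13e-05; adjusted p = 0.252 with an estimated correlation). Of 16 elastic fibre and microfibril genes 10 were lower and 2 higher (10 and 2 adjusted over the list alone; camera adjusted p = 0.0125, adjusted p = 0.252 with an estimated correlation). Mfap4, a microfibril-associated protein, was lower (-1.48 ± 0.13), as was Fbn1 (-0.87 ± 0.15), and Fbln2, a fibulin, was higher (2.87 ± 0.18). The crosslinking list had 6 lower and 1 higher of 16 (7 and 1 adjusted over the list alone; 5 and 0 with DESeq2; camera adjusted p = 0.0125, adjusted p = 0.252 with an estimated correlation), with the procollagen protease Adamts2 at -1.25 ± 0.24, Loxl1 at -1.08 ± 0.15 and Lox at -1.06 ± 0.15. Of 11 proteoglycan genes 8 were lower and 0 higher (8 and 0 adjusted over the list alone; camera adjusted p = 0.00287, adjusted p = 0.252 with an estimated correlation), with Acan, the large cartilage proteoglycan, at -1.20 ± 0.37 and Ogn at -1.19 ± 0.11. Of 16 heritable aortic disease genes 11 were lower and 3 higher (11 and 3 adjusted over the list alone; camera adjusted p = 0.0125, adjusted p = 0.277 with an estimated correlation).

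Basement membrane genes went both ways, with 5 of 14 higher and 5 lower (7 and 5 adjusted over the list alone). Nid1 was higher (3.49 ± 0.23) and Col18a1, a basement membrane collagen, lower (-1.12 ± 0.12). Of 14 protease and inhibitor genes 4 were higher and 4 lower (5 and 4 adjusted over the list alone; 3 and 2 with DESeq2), the higher ones including Timp4, a metalloproteinase inhibitor (4.18 ± 0.15), and Adamts9 (1.90 ± 0.23). Among 26 integrin and focal adhesion genes 14 were lower and 6 higher (16 and 6 adjusted over the list alone). Itga6, a laminin receptor chain, was higher (7.39 ± 0.21), as was Ptk2, the focal adhesion kinase (1.59 ± 0.19), and Itgb1 was lower (-0.58 ± 0.10). Of 14 mechanosensitive channel and receptor genes 3 were higher and 5 lower (3 and 5 adjusted over the list alone; 3 and 2 with DESeq2), and of 20 Hippo genes 4 were higher and 6 lower (4 and 6 adjusted over the list alone). Ankrd1 and Ccn2, targets of Yap1, were lower (-1.87 ± 0.43 and -1.11 ± 0.10), Amotl2, which binds Yap1, was higher (1.36 ± 0.15), and Yap1 did not pass (0.22 ± 0.19).

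In the TGF-beta list 8 of 16 were higher and 3 lower (8 and 3 adjusted over the list alone), with Tgfbr2 at 0.70 ± 0.14. Of 12 dissociation-stress genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone; 3 and 0 with DESeq2), among them Ier2 (1.26 ± 0.19) and Jun (1.06 ± 0.14).

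Here edgeR called 1293 of 7797 genes higher and 1475 lower, against 911 and 553 with DESeq2, and 43 higher and 80 lower among 189 genes of the fixed lists. A subcluster with 46.3% of endothelial-like cells carried smooth muscle transcripts (Acta2 12114 CPM, against 1278 in the next largest subcluster), and Hbb-bs stood at 11453 CPM in endothelial-like against 1138 in SMC-like cells. Without such subclusters the log2 fold change was -2.50 for Eln, -3.18 for Col3a1, -2.77 for Col1a1, -2.06 for Lox, -2.77 for Ccn2 and 2.85 for Piezo1. The call of Acan was lost in 7 of 17 alternatives (edgeR or DESeq2 adjusted p from 4.48e-05 to 0.456 over all of them), among them those without hashtag sample 1 and without 2, and that of Ankrd1 in 1, without hashtag sample 3 (3.64e-09 to 0.0677). The folds of 24 of 31 named genes moved by over 1.5 times in at least 1 alternative.

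**Figure D3:**
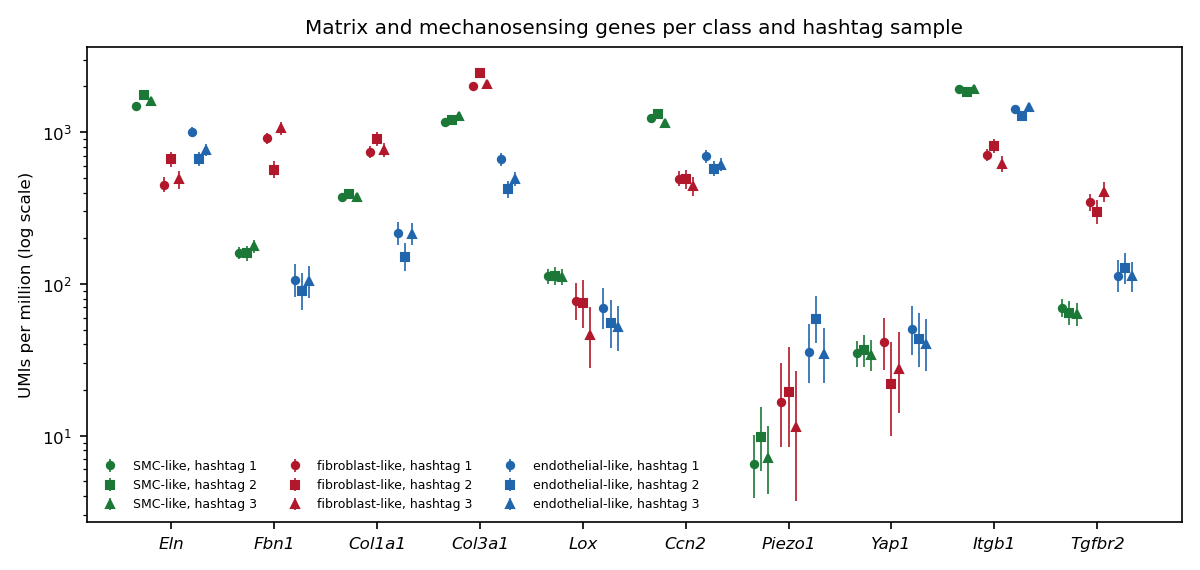
CPM (vertical axis, log scale) of matrix and mechanosensing genes (horizontal axis) in each cell class and hashtag sample. Points are single hashtag samples with Poisson 95% intervals; Eln stands at 1492 to 1755 CPM in SMC-like cells, above the endothelial-like and fibroblast-like samples.

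Resident immune cells take part in matrix turnover, and the comparison of macrophage-like with SMC-like cells asks how the same genes differ in them. The class is a mixture: Lyz2 and C1qa were each found in 45.1% of its cells, the T-cell gene Cd3e in 24.8% and Top2a, a gene of dividing cells, in 26.5%, against 3.72%, 2.32%, 0.0521% and 0.182% of SMC-like cells, so its values are not those of macrophages alone. The class also held more fibroblast and endothelial RNA than SMC-like cells, with Dcn at 1100 against 79.8 and Cdh5 at 59.2 against 1.32 CPM. Whether that RNA raised genes that were also higher in fibroblast-like or endothelial-like cells, such as Fbln1, Pcolce2, Nid1, Plxnd1 and Itga6, was not tested. Cells of this class had higher levels of the elastin-degrading cathepsin gene Ctss and of the integrins Itga6 and Itga4, and lower levels of most elastic fibre genes. They had lower levels of 8 of 14 basement membrane and 13 of 25 integrin and focal adhesion genes (7 and 10 with DESeq2). Ctss stood at 382 ± 156 CPM against 0.686 ± 0.599 in SMC-like cells, a log2 fold change of 8.62 ± 0.38 (adjusted p = 1.69e-17, edgeR quasi-likelihood, higher in 3 of 3 samples). Itga6 and Itga4 were higher, with log2 fold changes of 4.08 ± 0.56 and 3.63 ± 0.53, and Eln, Ccn2 and Itgb1 were lower (-1.10 ± 0.18, -1.29 ± 0.14 and -0.88 ± 0.12).

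Of 16 elastic fibre and microfibril genes 10 were lower in macrophage-like cells and 4 higher (11 and 4 adjusted over the list alone), and the set did not pass (camera adjusted p = 0.106). Emilin2 (4.47 ± 0.76) and Fbln1 (2.03 ± 0.39) were higher and Fbn1 lower (-0.97 ± 0.23). The fold of Emilin2 is set against only 5 UMIs in SMC-like cells. Of 12 interstitial collagen genes 8 were lower and 0 higher (8 and 0 adjusted over the list alone; camera adjusted p = 0.0117, adjusted p = 0.226 with an estimated correlation), with Col5a1 at -1.14 ± 0.25, Col6a2 at -1.01 ± 0.22, Col3a1 at -0.73 ± 0.15 and Col1a1 at -0.63 ± 0.16. Of 14 basement membrane genes 8 were lower and 2 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.0399, adjusted p = 0.209 with an estimated correlation). Nid1 was higher (2.72 ± 0.40), and Lamb1 had 10 UMIs against 1 UMI, a ratio of 118 in CPM (exact 95% counting interval 16.8 to 5138). Of 10 proteoglycan genes 4 were lower and 0 higher (5 and 0 adjusted over the list alone; camera adjusted p = 0.0399, adjusted p = 0.228 with an estimated correlation), with Prelp at -1.08 ± 0.19 and Bgn, the small proteoglycan biglycan, at -1.05 ± 0.14. Of 15 heritable aortic disease genes 8 were lower and 2 higher (8 and 2 adjusted over the list alone; 5 and 2 with DESeq2; camera adjusted p = 0.0399, adjusted p = 0.324 with an estimated correlation). Of 25 integrin and focal adhesion genes 13 were lower and 3 higher (15 and 3 adjusted over the list alone; camera adjusted p = 0.00714, adjusted p = 0.209 with an estimated correlation).

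The crosslinking list had 2 higher and 3 lower of 14 (2 and 5 adjusted over the list alone; 2 and 1 with DESeq2), with Pcolce2 at 1.71 ± 0.32, Lox at -0.87 ± 0.26 and Tgm2, a transglutaminase, at -0.98 ± 0.21. Of 15 protease and inhibitor genes 3 were higher and 4 lower (3 and 5 adjusted over the list alone), with the membrane-bound Mmp14 at -1.54 ± 0.58. Of 10 mechanosensitive channel and receptor genes 2 were higher and 4 lower (2 and 5 adjusted over the list alone; 2 and 2 with DESeq2). Plxnd1 (1.88 ± 0.41) and Piezo1 (1.37 ± 0.50) were higher and Piezo2 lower (-2.22 ± 0.60). Of 19 Hippo genes 1 was higher and 3 lower (1 and 3 adjusted over the list alone), with Ccn1 at -1.26 ± 0.19. Yap1 did not pass (-0.57 ± 0.40). Of 15 TGF-beta genes 2 were higher and 3 lower (3 and 4 adjusted over the list alone; 2 and 1 with DESeq2), with Tgfb1 at 0.91 ± 0.26, Tgfbr2 at 0.63 ± 0.24 and Tgfb3 at -1.17 ± 0.37. Notch1 was higher (2.57 ± 0.39). Of 12 dissociation-stress genes 2 were higher and 1 lower (3 and 1 adjusted over the list alone; 0 and 1 with DESeq2), with Egr1 at -1.52 ± 0.28.

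In the macrophage-like comparison edgeR called 912 of 7095 genes higher and 825 lower, and 25 higher and 68 lower among 179 genes of the fixed lists, from 19, 11 and 40 cells per hashtag sample, with Acta2 at 7412 and Hbb-bs at 8331 CPM in macrophage-like cells. Without hashtag sample 3, which holds most of these cells, 56 genes of the lists were called in place of 93, and the calls of Col1a1, Lox, Piezo1, Tgfbr2, Pcolce2, Plxnd1, Tgfb3 and Tgfb1 ended. RLE size factors, which moved the median of all genes by 0.11 on the log2 scale, gave 1053 and 601 and DESeq2 947 and 455. Calls of Mmp14 were lost in 12 of 15 alternatives, of Piezo1 in 9 and of Tgfbr2 in 6 (edgeR or DESeq2 adjusted p up to 0.273, 0.185 and 0.330 over all alternatives), and those of Col1a1, Lox, Tgfb1, Tgfb3, Pcolce2, Plxnd1, Piezo2, Itga6 and Egr1 in at least 1. Without sample 1 the calls of Lox, Piezo1, Mmp14, Piezo2 and Tgfb1 ended, and without sample 2 those of Piezo1, Tgfbr2 and Mmp14. The folds of 12 of 31 named genes moved by over 1.5 times in at least 1 alternative: Itga6 to a log2 of 0.83 (adjusted p = 0.163) at resolution 1.0, Egr1 to -0.37 with centring per cell, and Mmp14 and Piezo2 to -7.08 and -7.77 without sample 3.

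Within the SMC-like class, the second largest subcluster (195 cells) was compared with the largest (3532 cells) to ask whether matrix and mechanosensing genes vary within the class. The smaller one was led by Rgs5, a pericyte marker, and Adamtsl1, held 4 haemoglobin genes among its 10 leading genes and scored highest for erythroid (2.39) and pericyte markers (1.33), against 0.12 for smooth muscle markers. Its median haemoglobin share of UMIs was 0.0495%, against 0.0474% in the largest. Cells with over 1% made up 9.74% of it, against 2.46%, so the haemoglobin lead lay with a minority of its cells. The contrast can therefore reflect other cells or their RNA as well as variation among smooth muscle cells. The smaller subcluster had higher levels of 6 of 15 elastic fibre and microfibril genes and lower levels of 0 (9 and 0 adjusted over the list alone), among them Fbln1 (3.52 ± 0.55), Mfap5 (1.94 ± 0.18) and Eln (0.58 ± 0.14). Eln stood at 2656 ± 1035 against 1716 ± 86.0 CPM (adjusted p = 0.00727, edgeR quasi-likelihood, higher in 3 of 3 samples). The set was higher by limma camera (adjusted p = 3.59e-08; adjusted p = 0.628 with an estimated correlation). Col8a1, a short-chain collagen of the vessel wall, had 0 UMIs in the smaller and 321 in the larger subcluster, at least 4.49-fold lower (floor of 3 counts over the group).

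Other lists had few calls. Of 11 interstitial collagen genes 2 were higher and 1 lower (4 and 1 adjusted over the list alone), while Col1a1 and Col3a1 did not pass (0.10 ± 0.18 and -0.09 ± 0.14). The crosslinking list had 2 higher and 0 lower of 16 (3 and 2 adjusted over the list alone; 1 and 0 with DESeq2), with Pcolce2 at 2.03 ± 0.47 and Lox at 0.82 ± 0.24. Of 12 basement membrane genes 1 was higher, the laminin chain Lama2 (1.97 ± 0.46). Of 13 protease and inhibitor genes 1 was higher (1 higher and 1 lower adjusted over the list alone), Timp3 (0.60 ± 0.14). Of 13 mechanosensitive channel and receptor genes 1 was higher, Piezo1 (2.24 ± 0.67; 0 with DESeq2). Of 24 integrin and focal adhesion genes 2 were lower (5 lower and 1 higher adjusted over the list alone; 0 and 0 with DESeq2), with Itga5, the fibronectin receptor chain, at -1.60 ± 0.40. Of 9 proteoglycan genes 1 was higher and 2 lower (1 and 0 with DESeq2), with Aspn, the proteoglycan asporin, at -1.80 ± 0.37. Of 14 heritable aortic disease genes 2 were higher and 1 lower (3 and 2 adjusted over the list alone; 1 and 1 with DESeq2). None of 19 Hippo, 15 TGF-beta and 12 dissociation-stress genes passed. Values of Fbn1 (0.45 ± 0.23), Ccn2 (0.14 ± 0.14), Yap1 (0.03 ± 0.50), Itgb1 (-0.35 ± 0.13) and Tgfbr2 (-0.88 ± 0.43) did not pass.

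Between these subclusters edgeR called 99 of 7576 genes higher and 145 lower (70 and 32 with DESeq2), and 14 higher and 8 lower among 176 genes of the fixed lists, with 12, 13 and 10 cells of the smaller subcluster per hashtag sample. Haemoglobin Hbb-bs stood at 6177 CPM in the smaller against 885.6 in the larger subcluster and Pecam1, an endothelial gene, at 34.8 against 9.23. Calls were lost for Eln in 2 of 8 alternatives (edgeR or DESeq2 adjusted p from 0.000243 to 0.517), Piezo1 in 6, Lox in 5, Lama2 in 2, Pcolce2 in 2, Aspn in 1 and Itga5 in 3. Eln lost its call with DESeq2 and without hashtag sample 2, and without sample 3 the lists held 12 called genes in place of 22. Lox and Piezo1 lost theirs whichever sample was left out (adjusted p up to 0.416 and 0.502), Lama2 and Pcolce2 without sample 2 (0.239 and 0.275) or 3, and Itga5 without 1 (0.339) or 3. The folds of 4 of 18 named genes moved by over 1.5 times in at least 1 alternative.

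Fibroblast-like subclusters were compared in the same way, the second largest (249 cells, led by Akr1c18, Pla1a and Sema3c) with the largest (371 cells, led by Sfrp1, Gpx3 and Inmt). Cells of the second had higher levels of Fbn1 and of the TGF-beta genes Tgfb2 and Tgfbr2, and lower levels of Mfap4 and of the proteoglycan gene Bgn. Fbn1 stood at 2557 ± 436 against 445 ± 71.6 CPM, a log2 fold change of 2.53 ± 0.18 (adjusted p = 1.35e-07, edgeR quasi-likelihood, higher in 3 of 3 samples), Tgfb2 changed by 1.91 ± 0.41 and Tgfbr2 by 1.34 ± 0.23. Mfap4 and Bgn changed by -2.91 ± 0.32 and -1.45 ± 0.22.

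Of 13 elastic fibre and microfibril genes 4 were higher and 2 lower (4 and 3 adjusted over the list alone). Of 10 heritable aortic disease genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0353, adjusted p = 0.50 with an estimated correlation). Of 6 TGF-beta genes 2 were higher and 0 lower (1 and 0 with DESeq2). The list as a set was higher by camera (adjusted p = 0.0353; adjusted p = 0.50 with an estimated correlation). The crosslinking list had 3 higher and 2 lower of 9 (4 and 2 adjusted over the list alone; 1 and 1 with DESeq2), with Loxl2, a lysyl oxidase, at 2.81 ± 0.46. Of 9 interstitial collagen genes 2 were higher (1 with DESeq2), Col5a1 among them (1.34 ± 0.31), and Col1a1 (-0.39 ± 0.25) and Col3a1 (-0.14 ± 0.15) did not pass. Of 10 protease and inhibitor genes 2 were higher (2 higher and 1 lower adjusted over the list alone), with Adamts5, which cleaves proteoglycans, at 1.70 ± 0.22. Of 9 basement membrane genes 1 was higher (2 higher and 1 lower adjusted over the list alone), Nid1 (1.35 ± 0.17). Of 7 proteoglycan genes 2 were higher and 1 lower (0 and 1 with DESeq2). Of 8 integrin and focal adhesion genes 1 was higher, Zyx, a focal adhesion protein (1.52 ± 0.29), and of 5 Hippo genes 1, the receptor kinase Axl (1.55 ± 0.23). Of 3 dissociation-stress genes 1 was higher, Jun (1.21 ± 0.25; 2 adjusted over the list alone, 0 with DESeq2). None of 4 mechanosensitive channel and receptor genes passed. Eln (-0.17 ± 0.33), Ccn2 (-0.62 ± 0.36) and Itgb1 (0.29 ± 0.23) did not pass, and Lox, Piezo1 and Yap1 had too few counts to be tested.

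Here edgeR called 125 of 1724 genes higher and 83 lower (66 and 44 with DESeq2), and 20 higher and 5 lower among 94 genes of the fixed lists, with 26, 10 and 22 against 27, 16 and 16 cells per hashtag sample. Haemoglobin Hbb-bs stood at 8950 CPM in the second against 3442 in the largest subcluster, with a median of 6610 against 4825 UMIs per cell. Calls were lost for Col5a1 in 2 of 9 alternatives, Tgfb2 in 3, Jun in 4 and Zyx in 1. Each of these ended without hashtag sample 1 (edgeR adjusted p = 0.194, 0.0518, 0.0513 and 0.0627), and that of Tgfb2 also without sample 3 (0.0505). With ratio calls Jun had a log2 fold change of 0.16 (adjusted p = 0.819), and the folds of 4 of 17 named genes moved by over 1.5 times in at least 1 alternative.

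Whether genes differ between the animals could be described but not tested, with 1 sample per age. Eln stood at 1492, 1755 and 1611 CPM in the SMC-like cells of hashtags 1, 2 and 3 (11, 12 and 13 weeks), 1.18 times from lowest to highest, and the Poisson 95% intervals of these samples did not overlap. In SMC-like cluster 1 alone Eln ranged from 1290.3 to 1661 and in cluster 3 from 1830.5 to 1959 CPM. Fbn1 in fibroblast-like cells stood at 908, 565 and 1057 CPM, 1.87 times from lowest to highest. The subcluster with high Fbn1 held 26 of 96, 10 of 64 and 22 of 65 of these cells, in the same order. With ratio calls it held 18 of 70, 22 of 99 and 25 of 90, shares that lay closer together. A difference in the makeup of the class between the samples thus depended on the caller and was not tested. Of the 10 genes named in every comparison, the intervals of all 3 samples overlapped for 7 in SMC-like, 6 in fibroblast-like and 7 in endothelial-like cells, and for 8 in each of SMC-like clusters 1 and 3. Itgb1, Col1a1, Lox and Yap1 were among those that overlapped in SMC-like cells, and Lox at 112, 113 and 111 CPM differed least. Xist, transcribed from the inactive X chromosome, stood at 911, 935 and 937 CPM in the 3 hashtag samples, and 4 Y-linked genes had 0 UMIs in each, so the sexes of the animals gave no check of the hashtag calls.

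How strongly each class carried the hashtags sets which cells entered the comparisons. Endothelial-like cells had a median of 1268.5 hashtag UMIs, macrophage-like cells 1204, SMC-like cells 665 and fibroblast-like cells 657, and per 1000 gene UMIs the medians were 202.4 in endothelial-like and 83.6 in SMC-like cells. HTODemux assigned a single hashtag to 61.8% of endothelial-like (95% interval 56.8 to 66.5%) and 21.3% of SMC-like cells. The ratio caller assigned 87.0% (83.3 to 90.1%) and 26.3% (24.9 to 27.7%). With the ratio caller the share was 84.1% in macrophage-like, 92.9% in B-like, 66.7% in mesothelial-like, 42.4% in pericyte-like, 24.6% in erythroid-like, 23.2% in fibroblast-like and 10.8% in unnamed cells. Most SMC-like and fibroblast-like barcodes thus had hashtags near the background composition. Hashtags 2 and 3 were positive together 2.70 times as often as independent calls would give in SMC-like and 2.77 times in fibroblast-like cells, against 0.893 times in endothelial-like cells. Sums of SMC-like and fibroblast-like cells per hashtag can therefore mix animals, and their adjusted p-values hold only as far as the calls separate the animals.

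**Figure D4:**
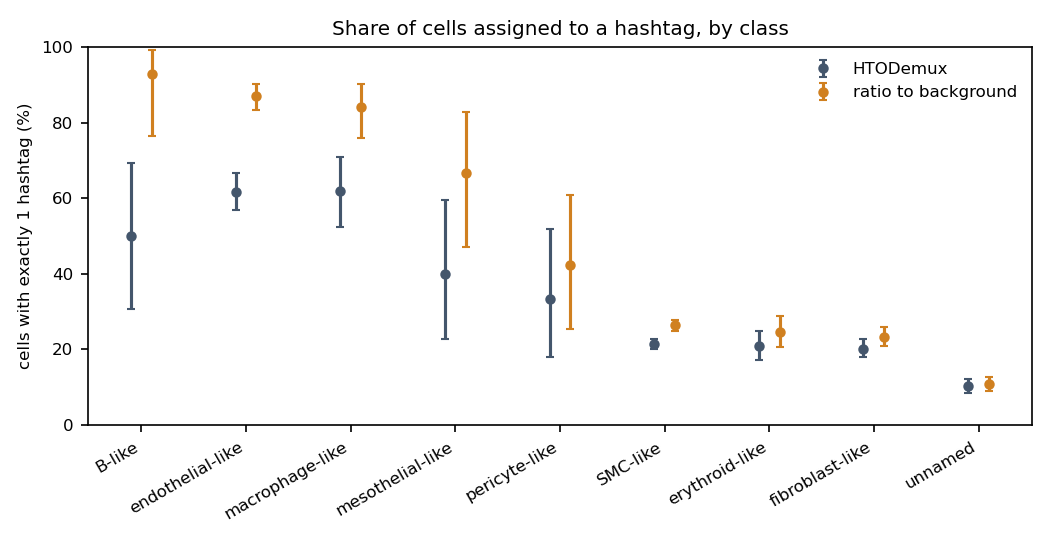
Share of cells with exactly 1 hashtag (%, vertical axis) in each class (horizontal axis), with HTODemux and with the caller on the ratio to background. Points carry exact 95% binomial intervals; with the ratio caller 87.0% of endothelial-like and 26.3% of SMC-like cells have a single hashtag.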

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

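Every test in this part was chosen after the result it bears on was seen, apart from the test of endothelial and immune cells attached to SMC-like cells, which was planned before but first run on the largest SMC-like subcluster and repeated on the whole class after that result was seen.

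Signals lay in barcodes that the comparisons do not use. At up to 20% mitochondrial UMIs, a cluster led by neutrophil and macrophage markers (S100a9, S100a8, Lyz2 and C1qa) had 535 barcodes outside the cell filter used for the comparisons, a mesothelial-marker cluster (Upk3b, Muc16 and Msln) had 314 and an adipocyte-marker cluster (Cfd, Car3, Ucp1) had 152. They are listed only because the comparisons leave them out, which says nothing of their origin. Barcodes with 10 or more but under 300 haemoglobin UMIs numbered 30652, or 63.2% of all barcodes.

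The share of cells with a single hashtag differed between classes far beyond counting error, at 87.0% in endothelial-like and 26.3% in SMC-like cells with the ratio caller. A candidate explanation is that the antibodies follow the level of MHC class I, yet fibroblast-like cells, with 2.83 times the H2-K1 and 2.70 times the H2-D1 level of SMC-like cells, had a share of 23.2%, which argues against transcript levels of these genes as the whole cause. Other classes went with it: mesothelial-like, endothelial-like, macrophage-like and B-like cells had H2-K1 at 1273, 887, 580 and 414 CPM. Their shares were 66.7%, 87.0%, 84.1% and 92.9%. H2-K1 stood at 399 CPM in fibroblast-like and 141 in SMC-like cells. Unnamed cells, at 226 CPM, had a share of 10.8% and went the other way. Called and uncalled barcodes were also compared within each class, with mixed subclusters left out. H2-K1 was 1.12 to 1.46 times as high in called barcodes of fibroblast-like and 1.11 to 1.21 times in those of SMC-like cells. In SMC-like cells H2-D1 was 0.973 to 1.10 and B2m 1.00 to 1.04 times as high (1.07 to 1.35 and 1.14 to 1.32 in fibroblast-like cells). A part of MHC class I in the difference thus stays open. Tags brought by endothelial or immune cells attached to SMC-like cells would raise markers of those cells in the called barcodes, and the highest ratio of called to uncalled over the 3 hashtags was 1.17; since barcodes with many such transcripts were clustered out of the class, this cannot be told apart from other origins. Loss of surface antigens in the digestion, which was not tested, and a difference between cell types in how they bind the antibodies stay open.

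The barcodes with a middle amount of haemoglobin RNA had a median of 2074 UMIs against 5418 in those with under 10 haemoglobin UMIs, and carried a single hashtag less often in many clusters: 11.1% against 93.2% in the neutrophil and macrophage cluster, 15.4% against 88.4% in the endothelial cluster led by Vwf, and 6.45% against 95.2% in the B cluster, while it was 77.9% against 94.0% in the endothelial cluster led by Gpihbp1 and 30.2% against 28.6% in the smooth muscle cluster. Free haemoglobin RNA at 1 common level in every droplet, at the middle barcodes' median of 67 UMIs, would leave few barcodes with under 10. Of all barcodes 27.7% held under 10, which argues against such a common level only. Free RNA at a level that differs between droplets or libraries stays open. The hashtag composition of uncalled barcodes differed by at most 0.624 percentage points between barcodes with little and with a middle amount of haemoglobin RNA. Uncalled barcodes are by definition those near 1 common background, so this cannot decide on a separate capture with another hashtag background. Whether these barcodes are damaged cells cannot be told apart from other origins: the Malat1 share of fibroblast-cluster barcodes was 1.27 times and the mitochondrial share 1.54 times as high as with little haemoglobin, against 0.933 and 0.979 times in the Gpihbp1 endothelial cluster. Separate captures, with a like or another background, stay open, since barcodes cannot be traced to the 4 libraries, and no biological explanation was tested.

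Smooth muscle transcripts stood 9.28 times apart between the 2 largest endothelial-like subclusters. Smooth muscle markers were not left out of the clustering and were among the leading genes of the mixed subcluster. A gap was thus built into the split, and it cannot decide whether free RNA is the origin. Barcodes that hold an SMC-like cell and another cell cannot be told apart from other origins: the share left of the endothelial markers and the share of the SMC marker level added up to 1.03 (0.995 for the fibroblast-like subcluster), with a median of 8679 against 4645.5 UMIs per barcode in endothelial-like and 8620.5 against 4825 in fibroblast-like cells, but hashtag UMIs, which a further cell should not lower, had a median of 1189 against 1607 in endothelial-like and 731 against 632 in fibroblast-like cells. Random pairs from the pooled animals would give several hashtags on 5.02% of simulated sums, and 2.70% of the mixed endothelial-like barcodes (5 of 185, exact 95% interval 0.883 to 6.19%) had them by the ratio caller. That interval also covers the 3.54% of the other endothelial-like subclusters, so random pairs and pairs from 1 animal, such as pieces of undigested wall, stay open. No biological explanation, such as a cell state between the classes, was tested.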

How the results depend on the processing

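Of the alternatives, 61 values were planned before the data were examined (49 within the limits for an unchanged result, 12 moved) and 40 were chosen after seeing the data (32 and 8), as were the splits of the samples given last. These values are counts, shares and ratios without a direction. None of 2096 values for the named genes had a called direction turned: 1986 stayed on their side of the threshold, 105 lost the call and 5 gained one. Called named genes kept the call in all alternatives for 28 of 31 genes in the fibroblast-like, 28 of 30 in the endothelial-like and 18 of 30 in the macrophage-like comparison. This held for 4 of 11 between SMC-like subclusters, 8 of 12 between fibroblast-like subclusters and 8 of 12 between SMC-like clusters 3 and 1. Counts of called fixed-list genes ranged from 108 to 143 for fibroblast-like (131 in the report), 91 to 147 for endothelial-like (43 higher and 80 lower in the report) and 56 to 106 for macrophage-like cells (93).

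Without 1 hashtag sample the macrophage-like count was 56 to 85 and the SMC-like subcluster count 12 to 22 (22 in the report), both lowest without sample 3. DESeq2 called 14 genes between SMC-like subclusters, 16 between fibroblast-like subclusters (25 in the report) and 12 between SMC-like clusters 3 and 1 (29). With an estimated correlation limma camera called 0 lists against 16 in the 5 planned comparisons, or 7 of 65 at an unadjusted p under 0.05 (0 against 17 of 78 with clusters 3 and 1). Without the hashtag block the preset correlation gave 17 in the planned ones. The SMC-like share of 51.0% was 58.5% at resolution 1.0, 29.9% with the stricter cell filter, 44.3% with mixture calls, 49.9% with ratio calls, 22.9% with centring per cell, 31.4% at up to 20% mitochondrial UMIs and 60.5% in cells with under 10 haemoglobin UMIs. The single-hashtag share of 22.5% was 19.2% with mixture calls, 18.8% at the higher positive quantile, 32.6% with the stricter filter, 11.4% with centring per cell, 28.1% with ratio calls and 16.4% at up to 20% mitochondrial UMIs. The ratio of median hashtag UMIs, endothelial-like over SMC-like, was 1.91 (1.78 to 2.06) and 2.42 per 1000 gene UMIs. The cause of these differences was not tested. The lower counts without a hashtag sample come with fewer samples.

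Not run were the stricter cell filter in class comparisons (178 cells), centring per cell for fibroblast-like cells, the low-haemoglobin filter for macrophage-like cells, mixture calls for subclusters and ratio calls for SMC-like subclusters, for too few cells, and the 20% filter for macrophage-like cells, whose cluster stayed unnamed by the naming rule. The 3-against-3 splits of the sums, without the block, are too few (10) for a share under 0.05: only 1 of 10, the real one, gave as many genes in each comparison. The real splits called 3150, 2952, 1781, 296, 211 and 378 genes (fibroblast-like, endothelial-like, macrophage-like, SMC-like subclusters, fibroblast-like subclusters, clusters 3 and 1) and the others at most 0, 0, 0, 0, 0 and 2. Every other split puts sums of both classes into each group, which widens the spread within groups. Few calls there follow from this, and the splits do not measure chance. With these depths and cell numbers, whose parts were not separated, simulations recovered 23% of 2-fold changes between SMC-like and 54% between fibroblast-like subclusters.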

Other observations

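The comparison of SMC-like clusters was chosen after the clusters were seen, and its tests, as well as its alternatives, were chosen with it. Between the 2 largest SMC-like clusters, the one led by Pln and Mgp (cluster 3) had higher levels of 7 of 14 elastic fibre and microfibril genes and of Timp1 than the one led by Tnnt2 and Ptprz1 (cluster 1). Timp1, an inhibitor of metalloproteinases, stood at 93.8 ± 44.1 against 6.42 ± 3.85 CPM (mean ± SD, n = 3), a log2 fold change of 3.87 ± 0.23 (adjusted p = 4.28e-20, edgeR quasi-likelihood, higher in 3 of 3 samples). Acan, the large proteoglycan of cartilage, changed by 2.84 ± 0.27, Fbln2 by 1.68 ± 0.32, the stretch-gated channel gene Piezo2 by 1.49 ± 0.21 and Col8a1 by 1.00 ± 0.17. Changes in Eln (0.37 ± 0.05), Col1a1 (0.40 ± 0.07), Fbn1 (0.42 ± 0.10) and Col18a1 (0.31 ± 0.06) were smaller.

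Of 14 elastic fibre and microfibril genes 7 were higher in cluster 3 and 1 lower (7 and 1 adjusted over the list alone; 2 and 1 with DESeq2). The set was higher by limma camera (adjusted p = 0.0127; adjusted p = 0.715 with an estimated correlation). Of 11 interstitial collagen genes 3 were higher (4 adjusted over the list alone), of 13 protease and inhibitor genes 2 (3 adjusted over the list alone), with 0 lower in both. Of 12 basement membrane genes 1 was higher and of 13 mechanosensitive channel and receptor genes 1, with 0 lower in both. Of 25 integrin and focal adhesion genes 2 were lower (6 adjusted over the list alone), with Itga8 at -0.28 ± 0.05. Of 19 Hippo genes 1 was lower (1 higher and 1 lower adjusted over the list alone), Tead1 (-0.38 ± 0.12). Of 9 proteoglycan genes 2 were higher and 2 lower, of 15 heritable aortic disease genes 2 and 1, and of 12 dissociation-stress genes 2 and 1 (3 and 8 adjusted over the list alone), with Ier2 at 0.83 ± 0.17. None of 16 crosslinking and 16 TGF-beta genes passed, nor did Col3a1 (-0.02 ± 0.06), Lox (0.09 ± 0.13), Ccn2 (0.17 ± 0.06), Yap1 (0.23 ± 0.20), Itgb1 (-0.10 ± 0.05) or Tgfbr2 (-0.12 ± 0.16). With DESeq2 no other list given here had more than 1 gene higher or 1 lower. In all, edgeR called 219 of 8059 genes higher and 208 lower (41 and 58 with DESeq2), and 18 and 11 among 177 genes of the fixed lists. Calls were lost for Tead1 in 6 of 8 alternatives (edgeR or DESeq2 adjusted p from 0.0132 to 0.625), Fbn1 in 3, Col18a1 in 1 and Ier2 in 1. Those of Tead1 and Fbn1 ended without hashtag sample 2 or 3, and that of Col18a1 without sample 1.

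A small endothelial-like subcluster of 17 cells carried lymphatic markers. The series lists 4 gene expression and 4 hashtag libraries, whose numbers do not map to barcodes, so no value is given per library. About 15000 cells were loaded per sample, and the labels do not say whether that means an animal or a library.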
